A study of Mus musculus with 10 samples.

How the data were processed

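Poly(A) RNA of whole skin from 10 mice aged 22 weeks was measured by RNA sequencing in 5 wildtype siblings (WT) and 5 homozygous mutants (NPYtet) of the B6;129S4-Npytm2Rpa/J strain, 1 library per mouse. Group, replicate number and sex were taken from the labels. Per the labels' protocols, RNA was extracted with TRIzol and a column kit and made into strand-specific paired-end libraries with a directional kit. Each deposited file holds whole-number read counts per Ensembl gene ID in a single count column. Per the submitters' processing notes, reads were handled with bcl2fastq, FastQC 0.11.8, Trimmomatic 0.36, STAR 2.5.2 and DESeq2 1.30.1 on the mm10 build. Which strand column of the aligner's output the deposited counts come from, and the annotation release, are not given in the sources used here.

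The 10 files hold the same 49671 gene IDs, of which 49412 matched the GENCODE M21 annotation (GRCm38, the assembly of mm10). The other 259 IDs took 0.019% of reads. No file holds rows of unassigned reads. Total counts ran from 23209405 (NPYtet replicate 5) to 53357695 (WT replicate 4), and a gene with 0 reads in a library is compatible with up to 3 reads, a limit that covers counting error only. A chi-square comparison of every pair of libraries of 1 group found no pair within sampling noise, so each library was counted once.

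Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on genotype, with a minimum count of 10 and a minimum total of 15, which left 18060 genes. Library sizes were scaled by TMM, and the robust quasi-likelihood test (glmQLFit, glmQLFTest) was fitted to sex and genotype, with p-values adjusted by Benjamini and Hochberg and a threshold of 0.05. Fold changes are log2 and signed as NPYtet minus WT, or as male minus female. The sex term uses the label of every library, including 1 whose X- and Y-linked reads go against it. No fit counted that library as male. A model of the 4 combinations of genotype and sex gave the genotype difference within each sex and the difference between those differences. CPM expresses counts relative to the scaled library size, and log2 CPM adds a prior count of 2. Means are given with the SD over 5 libraries.

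The 53 gene lists, covering skin and immune cell types and pathways, were fixed before the data were examined, as were the comparisons, the rule for naming genes and the alternatives, apart from those named below as chosen later. Of 1034 names in the lists, 9 did not match the annotation. Some genes belong to several lists, so results of lists that share members are not separate. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The other alternatives for lists kept the preset correlation. A list score is the mean over members of log2 CPM after subtracting each member's mean over the 10 libraries. Scores and Npy itself were compared between groups with two-sided exact permutation tests over the 252 divisions of the 10 libraries, whose smallest possible p is 0.00794.

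By the naming rule, a genotype gene could be named as a detected member of the NPY system list, as a called gene, as 1 of the 10 genes with the smallest p among those of mean CPM of at least 1 with a full gene symbol and outside immune receptor segments, or as 1 of up to 4 members with the smallest p in each list. From the last group, the members of the lists described were printed in part. The other members of the pigment list were named after their values were seen. For sex, the rule takes the 5 called genes with the highest and the 5 with the lowest log2 fold change among those of mean CPM of at least 1 and with no overlap between the sexes. S100a8, S100a9 and Alox15 were added for sex after their values were seen.

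Genes whose reads come from near-identical copies (Stfa and Sprr families, Krtap genes, immunoglobulin segments, Lce1l and Lce1m, Hamp and Hamp2) are uncertain in how their reads were split between copies, and antisense partners likewise, since the strand setting is not given in the sources used here. The fit was tested on simulated counts for the genotype comparison, with 50 genes changed at each size over 18060 genes: 3 of 50 genes changed 2-fold were recovered, 33 at 4-fold, 47 at 8-fold and 49 at 32-fold, with 2 false calls. Simulated counts were drawn independently for each gene, without sex or tissue differences between libraries. The changed genes had a mean CPM of at least 1.

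Alternatives were DESeq2 1.42.0, limma voom with quality weights, other scaling, looser and stricter filters on low counts, no sex term, a replicate block, tissue scores as covariates and leaving out each library in turn. Chosen after seeing the data were the removal of the libraries named in the report as standing apart, and covariates for the ribosomal RNA share and for the number of genes with a read after thinning every library to the smallest total. The alternative of an unstranded count column was not run, since each file has 1 count column. Other divisions of the 10 libraries were drawn 100 times, the real one included. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.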

Results

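The study asked how the skin transcriptome differs between mice homozygous for an altered Npy allele and their wildtype siblings, and its title links the difference to inflammation of the skin. Npy encodes neuropeptide Y, a peptide of brain neurons and sympathetic nerves. Whole skin was sequenced from 5 WT mice (labelled 2 female, 3 male) and 5 NPYtet mice (labelled 3 female, 2 male), all aged 22 weeks. In WT replicates 1 to 5 the total counts were 33101744, 27207273, 36564449, 53357695 and 37549830 reads. In NPYtet replicates 1 to 5 they were 37941704, 30509404, 36025838, 36730373 and 23209405 reads.

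Krt14, Col1a1 and mitochondrial transcripts were among the most abundant, and 3 libraries stood apart from the rest. In NPYtet replicate 5, mitochondrial genes took 9.26% of reads (1.86% to 3.03% in the others), the ribosomal RNA locus took 4.70%, and 19953 genes had a read, the fewest of any library. WT replicate 2 had 1.82% of reads at the ribosomal RNA locus, against at most 0.44% in the 8 libraries other than these, and 21144 genes with a read. Their scaling factors were the lowest, 0.652 and 0.696. NPYtet replicate 1 is labelled female but had 2 reads of Xist, the RNA of the inactive X chromosome, at 0.049 CPM. The other 4 libraries labelled female had 333 to 462 CPM. It held 1513 reads of the Y-linked gene Ddx3y, or 37.2 CPM, within the 18.1 to 67.5 CPM of the libraries labelled male, while the other 4 labelled female had 0 reads of Ddx3y. Npy was at 96.2 CPM in it. It is called the library labelled female below, and each direction drawn from sex labels includes it.

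Npy differed most clearly between the genotypes. It averaged 1.57 ± 1.03 CPM in WT (SD, n = 5) and 224 ± 156 CPM in NPYtet (SD, n = 5), and rose by 7.45 on the log2 scale (SE 0.62, edgeR adjusted p = 0.000109), being higher in 5 of 5 NPYtet libraries. The gene lies on chromosome 6 at 49822710 to 49829507 (mm10, forward strand, ENSMUSG00000029819). WT replicates 1 to 5 held 54, 54, 4, 80 and 73 reads of it, and NPYtet replicates 1 to 5 held 3913, 7686, 7187, 5661 and 7336. The exact permutation test gave p = 0.00794, the smallest it can give. Of the NPY system list, 5 members were tested. Npy4r and Npy1r, receptors of the peptide family, had log2 fold changes of -0.41 (SE 0.44) and 0.24 (SE 0.58). With each library left out in turn, Npy4r ran from -0.674 to -0.178 and Npy1r from 0.023 to 0.786. Dpp4, a protease that trims neuropeptide Y, was at 0.14 (SE 0.36) and Pyy, a related gut peptide, at 0.09 (SE 0.999); none of these 4 passed (edgeR adjusted p = 0.999 each), and the receptor gene Npy2r had 0 reads. The list passed by camera in limma (adjusted p = 8.23e-07, mean 1.502, median 0.14) through Npy, its 1 called member; its adjusted p = 0.176 with an estimated correlation.

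**Figure D1:**
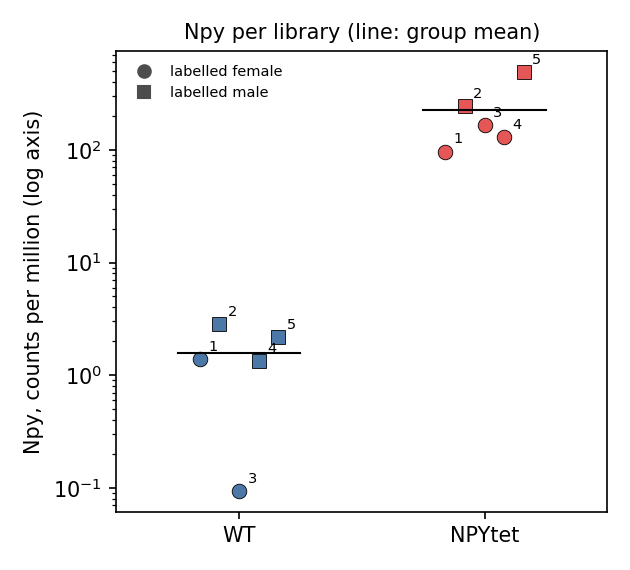
Npy in CPM (log axis) in each of the 10 libraries, by genotype, with replicate numbers beside the points, marker shape for the sex label and a line at each group mean (1.57 and 224 CPM). Every NPYtet library lies above every WT library, and WT replicate 3 is the lowest.

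Npy was the only 1 of 18060 genes past the threshold by genotype in edgeR, and 649 genes had an unadjusted p under 0.05, 263 higher and 386 lower in NPYtet. DESeq2 called 35 genes, 4 higher and 31 lower, limma voom called 2, and edgeR with no filter on low counts called 409, 83 higher and 326 lower. The groups did not overlap in 55 genes, or 0.30% of those tested, against 0.79% by chance. Leaving out WT replicate 3 gave 8 calls, 7 of them lower. Without WT replicate 2, NPYtet replicate 1 and NPYtet replicate 5 together, 0 genes were called in edgeR, and Npy had a log2 fold change of 7.45 (edgeR adjusted p = 0.133, within 1.20e-51 to 0.133 over all alternatives).

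Pigment genes were lower in NPYtet skin. Of 13 measured members of the melanocyte and pigment list, 11 had negative fold changes, and the list fell by camera in limma (median -1.27, adjusted p = 7.01e-11; adjusted p = 0.223 with an estimated correlation). Pmel, which forms the fibrils of pigment granules, averaged 39.2 ± 30.3 CPM in WT and 4.14 ± 1.29 CPM in NPYtet (SD, n = 5 each), a log2 fold change of -3.35 (SE 0.57, edgeR adjusted p = 0.306). Tyrp1 and Dct, enzymes of melanin synthesis, had -4.40 (SE 0.82, edgeR adjusted p = 0.655) and -3.58 (SE 0.72, edgeR adjusted p = 0.744), and Trpm1, a channel of melanocytes, had -3.94 (SE 0.92). All 4 were lower in 5 of 5 NPYtet libraries than in any WT library. No member passed over all genes in edgeR, and 6 were lower when adjusted over the list alone. The list score differed by -1.44 (exact permutation p = 0.00794, or 0.210 after adjustment over the 53 lists). WT replicates 1 to 5 scored 2.061, -0.049, -0.224, 1.723 and 0.099, so replicates 1 and 4 stood well above the other WT libraries. NPYtet replicates 1 to 5 scored -0.596, -0.798, -0.547, -0.655 and -1.015.

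**Figure D2:**
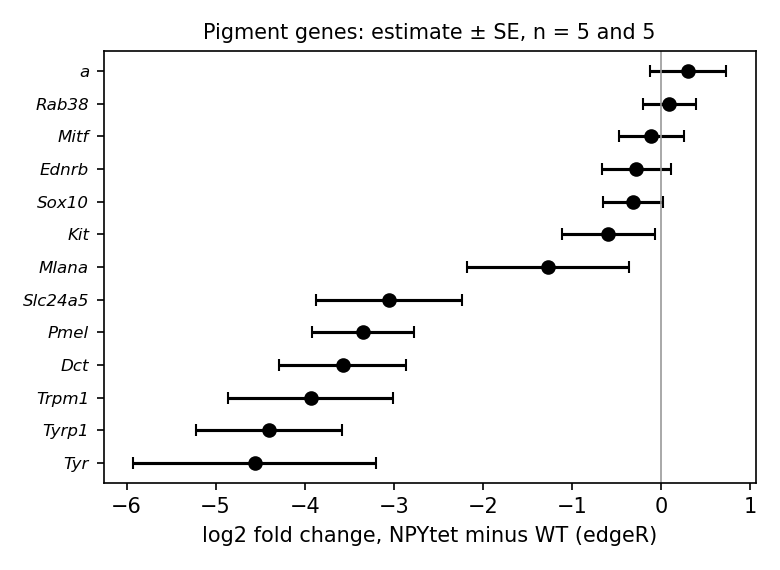
Log2 fold change, NPYtet minus WT, with its SE from edgeR, for the 13 measured genes of the melanocyte and pigment list (n = 5 libraries per genotype). Estimates run from -4.56 for Tyr to 0.30 for a, and 11 of the 13 lie below 0.

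Hair shaft and inner root sheath genes, which are made by growing follicles, were lower as a group in NPYtet. All 43 measured members had negative fold changes, and the list fell by camera in limma (median -4.04, adjusted p = 6.06e-26; adjusted p = 0.358 with an estimated correlation), with 0 members called over all genes by edgeR, 9 at unadjusted p under 0.05 and 6 lower when adjusted over the list alone. Lef1 and Msx2, transcription factors of the hair matrix, had log2 fold changes of -3.13 (SE 0.73) and -2.61 (SE 0.62). Hoxc13, a regulator of hair keratins, had -2.20 (SE 0.58), and the sheath keratin Krt74 had -4.08 (SE 1.06). DESeq2 called 6 genes of this list and 4 of the pigment list. Reads of the hair list made up 4.06%, 2.49%, 0.05%, 2.87% and 1.06% of WT libraries 1 to 5, and 0.01%, 0.23%, 0.03%, 0.02% and 1.57% of NPYtet libraries 1 to 5, so WT replicate 3 sat among the NPYtet libraries and NPYtet replicate 5 among the WT libraries. The cell cycle list fell too, with 32 of 32 members lower (median -0.89, camera in limma adjusted p = 1.72e-17; adjusted p = 0.336 with an estimated correlation). Plk1 and Cdk1, kinases of mitosis, had -1.10 (SE 0.34) and -0.89 (SE 0.34), and Mcm5, a part of the replicative helicase, had -1.06 (SE 0.38).

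Of the 10 genes with the smallest p under the naming rule, which asks for a mean of at least 1 CPM, the 9 besides Npy were lower in NPYtet, and 6 of them are outside these lists. Hes2, a transcriptional repressor, had a log2 fold change of -3.43 (SE 0.61, edgeR adjusted p = 0.306), and Dlx3, a homeobox gene of hair and epidermis, had -2.31 (SE 0.51, edgeR adjusted p = 0.744). Dclk3, Lrrc75b, Cdh6 and Ephb1 had -2.82, -2.81, -3.14 and -2.43 (edgeR adjusted p = 0.744, 0.744, 0.744 and 0.801). Over the alternatives the smallest declines were -2.004 for Hes2, -1.376 for Dclk3 and -1.665 for Cdh6. Without WT replicate 1 the medians were -0.91 for the hair list, -0.51 for the pigment list and -0.53 for the cell cycle list. All were still past the threshold of camera at its preset correlation of 0.01. Over all 10 libraries the estimated correlations were 0.886, 0.284 and 0.527, and none of these lists passed with them. Passing at the preset value therefore does not measure variation between mice. In the same fit Lef1 was at -1.97, Msx2 at -1.33, Hoxc13 at -0.97, Krt74 at -2.09, Dlx3 at -1.30, Lrrc75b at -1.50, Ephb1 at -1.35, Plk1 at -0.73, Mcm5 at -0.68 and Cdk1 at -0.54. With the hair score as a covariate Pmel was at -2.04, Tyrp1 at -2.48, Dct at -2.52 and Trpm1 at -1.93, and in limma voom Pmel was at -1.61 and Dct at -1.71. With each library left out in turn the pigment median lay between -3.32 (without NPYtet replicate 2) and -0.51. It was -0.32 with a replicate block and -0.50 with the white adipocyte score as a covariate, still past the threshold of camera at the preset correlation. In the main fit 6 members lie at -3.06 or lower: Tyr, Tyrp1, Dct, Pmel, Slc24a5 and Trpm1. The other 7, Mlana, Kit, Sox10, Ednrb, Mitf, Rab38 and a, lie between -1.27 and 0.30, with Mitf at -0.11 and Sox10 at -0.32.

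Genes of adipose tissue and lipid synthesis were higher as groups in NPYtet. In the white adipocyte list 19 of 20 members were positive, and the list rose by camera in limma (median 0.64, adjusted p = 9.54e-09; adjusted p = 0.358 with an estimated correlation). Retn, the gene of resistin, had a log2 fold change of 1.34 (SE 0.41), Lpl, the lipase of capillary walls, had 1.33 (SE 0.59) and Fabp4, a fatty acid carrier, had 1.03 (SE 0.46). The lipogenesis list rose, with 15 of 17 members positive (median 0.43, limma adjusted p = 0.000204; adjusted p = 0.252 with an estimated correlation), and Thrsp, a lipogenic factor, had 1.66 (SE 0.80). Thermogenic adipocyte genes rose, with 10 of 11 positive (median 0.32, limma adjusted p = 0.00925; adjusted p = 0.223 with an estimated correlation), and Kcnk3 had 1.53 (SE 0.60). The sebaceous gland list rose with 14 of 18 positive (median 0.43, limma adjusted p = 0.00152; adjusted p = 0.358 with an estimated correlation); Dgat2l6, an acyltransferase, had 0.97 (SE 0.30), and the desaturase Fads2 went the other way at -1.40 (SE 0.39). Cholesterol biosynthesis rose with 19 of 20 positive (median 0.22, limma adjusted p = 0.0125; adjusted p = 0.358 with an estimated correlation). Fatty acid oxidation fell, with 15 of 20 lower (median -0.25, limma adjusted p = 0.0219; adjusted p = 0.358 with an estimated correlation). No gene of these 6 lists was called over all genes by edgeR or when adjusted over the list alone, and 9 had an unadjusted p under 0.05. Leaving out WT replicate 1 gave medians of 0.41 for white adipocyte and 0.28 for lipogenesis genes, and the white adipocyte median was 1.02 without WT replicate 2. Without NPYtet replicate 5, Lpl was at 0.70, Fabp4 at 0.36 and Kcnk3 at 0.78, and without WT replicate 1 Thrsp was at 0.96 and Fads2 at -0.90. The sebaceous list lost its call without WT replicate 1 (median 0.33), the thermogenic list without NPYtet replicate 5 (0.21), cholesterol biosynthesis without WT replicate 3 (0.18), NPYtet replicate 1 (0.09) or NPYtet replicate 2 (0.15), and fatty acid oxidation without WT replicate 2 (-0.23), WT replicate 3 (-0.26) or NPYtet replicate 5 (-0.14).

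Several immune lists were higher in NPYtet. The B and plasma cell list rose by camera in limma, with 13 of 15 members positive (median 0.78, adjusted p = 2.79e-07; adjusted p = 0.256 with an estimated correlation); Ighm, the heavy chain of IgM, had a log2 fold change of 1.19 (SE 0.36) and Jchain, which joins antibody units, had 2.74 (SE 0.89). The eosinophil and type 2 list rose, with 16 of 17 positive (median 0.45, limma adjusted p = 3.22e-05; adjusted p = 0.223 with an estimated correlation) and 1 member higher when adjusted over the list alone. Its members Ccl24, a chemokine of eosinophils, and Retnla, a product of macrophages exposed to type 2 cytokines, had 1.22 (SE 0.34) and 1.91 (SE 0.59). Chemokines rose with 27 of 30 positive (median 0.49, limma adjusted p = 0.000204; adjusted p = 0.358 with an estimated correlation). Dendritic and Langerhans cell genes rose with 16 of 18 positive (median 0.22, limma adjusted p = 0.00286; adjusted p = 0.401 with an estimated correlation), among them Cd209a at 0.98 (SE 0.39). MHC class II genes rose with 12 of 12 positive (median 0.34, limma adjusted p = 0.0112; adjusted p = 0.642 with an estimated correlation). Complement rose with 15 of 19 positive (median 0.21, limma adjusted p = 0.0126; adjusted p = 0.468 with an estimated correlation), with C6 at 0.95 (SE 0.39). Without NPYtet replicate 5, Jchain was at 1.17 and Retnla at 1.01, without NPYtet replicate 2 the chemokine median was 0.15, and without WT replicate 3 that of the eosinophil list was 0.82. With the hair score as a covariate, B and plasma cell genes still passed, and the calls of the eosinophil (median 0.30), chemokine (0.04), dendritic (-0.07), MHC class II (0.105) and complement (-0.18) lists ended; the hair score is itself tied to genotype. Dendritic cell genes lost their call without WT replicate 1 (median 0.06), MHC class II without WT replicate 1 (0.15), WT replicate 4 (0.23), NPYtet replicate 1 (0.27) or NPYtet replicate 5 (0.17), and complement without WT replicate 1 (0.02), WT replicate 4 (0.11) or NPYtet replicate 2 (0.18).

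Inflammatory cytokine and NF-kB response genes rose as a list in the fit with the sex term, with 27 of 31 members positive (median 0.33, camera in limma adjusted p = 0.0149; adjusted p = 0.642 with an estimated correlation). The list score, taken without the sex term, differed by only 0.02 between the genotypes (exact permutation p = 0.968). Casp1, which activates interleukin 1 family cytokines, had a log2 fold change of 0.95 (SE 0.41) and Il18 had 0.84 (SE 0.38); without NPYtet replicate 5 they were at 0.22 and 0.19. NPYtet replicate 2 stood far above the other NPYtet libraries in this list's score, and without it the median was -0.18; the call was lost without WT replicate 1 (0.20) or WT replicate 4 (0.21), and with the hair score as a covariate (-0.11). The interferon response list did not pass (28 of 47 positive, median 0.07, mean -0.001, test direction down, limma adjusted p = 0.515), nor did the neutrophil list (9 of 11 positive, median 0.37, limma adjusted p = 0.427) or the type 17 axis (9 of 12 positive, median 0.29, limma adjusted p = 0.546). Keratinocyte activation genes, induced in wounded and inflamed epidermis, were divided 14 to 13 (median 0.05, test direction down, limma adjusted p = 0.718). T cell, macrophage and skeletal muscle lists did not pass either, at medians of 0.17, 0.09 and -0.14 (limma adjusted p = 0.140, 0.179 and 0.954). Without NPYtet replicate 5 the neutrophil, type 17, interferon, keratinocyte activation and macrophage lists passed upward (medians 0.82, 0.62, 0.23, 0.45 and 0.19), as they did without WT replicate 2 as well (0.76, 0.60, 0.16, 0.38 and 0.18). The interferon and keratinocyte activation lists passed downward without NPYtet replicate 2 (-0.48 and -0.72), with the hair score as a covariate (-0.24 and -0.54) and with a replicate block (-0.11 and -0.44), and the type 17 list also passed downward with the hair score (-0.38), so their direction rests on single libraries and on the fit. Macrophage genes also passed upward without WT replicate 3 (0.24) or WT replicate 5 (0.20), and T cell genes without WT replicate 3 (0.34), WT replicate 5 (0.18) or NPYtet replicate 4 (0.23). In all, T cell genes passed in 5 of 26 alternatives. Keratinocyte activation genes passed in 8 of 26, with medians over all alternatives from -1.015 to 0.447.

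Barrier and matrix genes were also higher. The cornified envelope list rose, with 25 of 31 members positive (median 0.55, camera in limma adjusted p = 3.44e-06; adjusted p = 0.358 with an estimated correlation); Lce1l and Lce1m, late cornified envelope proteins, had 1.02 (SE 0.33) and 1.04 (SE 0.38). Antimicrobial protein genes rose, with 12 of 14 positive (median 0.80, limma adjusted p = 0.00683; adjusted p = 0.358 with an estimated correlation), yet S100a7a had -2.70 (SE 1.05). Dermal fibroblast and matrix genes rose with 21 of 26 positive (median 0.33, limma adjusted p = 0.00291; adjusted p = 0.358 with an estimated correlation), with the crosslinking enzyme Lox at 1.25 (SE 0.41) and the collagen-binding Lum at 1.10 (SE 0.41). Without NPYtet replicate 5 the cornified envelope median was 0.27, Lce1l was at 0.62, Lce1m at 0.51, Lum at 0.50 and the antimicrobial median at 0.36, and without WT replicate 1 S100a7a was at -0.78. Over all alternatives the lowest values were 0.293 for Lox and 0.264 for Lum. Antimicrobial genes lost their call without WT replicate 4 (median 0.58), and matrix genes without WT replicate 4 (0.39), NPYtet replicate 1 (0.14) or NPYtet replicate 2 (0.24). The antimicrobial score, taken without the sex term, differed by -0.059 between the genotypes (exact permutation p = 0.944). No gene of the immune, barrier and matrix lists was called over all genes by edgeR. In all, 20 of the 53 lists passed, 16 up (the NPY system list among them) and 4 down, and 0 passed in limma with an estimated correlation or with fry. No list score passed after adjustment over the 53 lists (smallest exact permutation adjusted p = 0.210). With so few divisions a score could pass only if several lists reached the smallest possible p, so this result cannot decide. Unadjusted exact permutation p was 0.024 for lipogenesis, 0.032 for thermogenic adipocyte and 0.079 for hair scores. It was 0.111 for cell cycle, white adipocyte and B and plasma cell scores, 0.135 for eosinophil, 0.302 for MHC class II and 0.524 for chemokine scores. The division by direction moved with the fit: 6 up and 8 down with the hair score as a covariate, 11 up and 4 down with the white adipocyte score, 12 up and 8 down with a replicate block and 15 up and 8 down with no sex term. The hair covariate also ended the calls of the lipogenesis, sebaceous, thermogenic, cholesterol, antimicrobial and matrix lists, and the adipocyte covariate those of the cornified envelope list (median 0.20, limma adjusted p = 0.265) and of the antimicrobial, thermogenic, MHC class II, complement and fatty acid oxidation lists. With no sex term, the antimicrobial (median 0.27), cholesterol (0.09) and NF-kB (0.16) lists did not pass. Without NPYtet replicate 5, 32 lists passed.

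**Figure D3:**
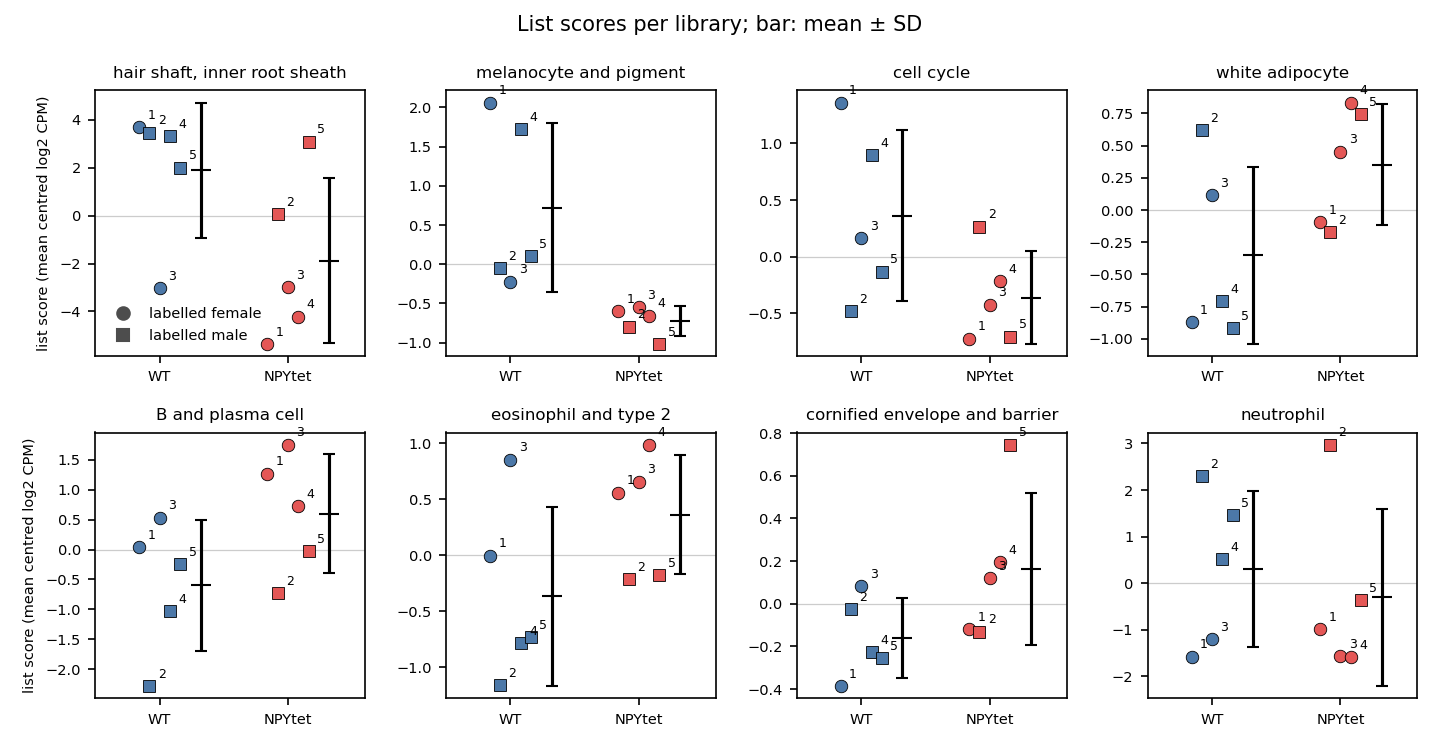
Scores of 8 gene lists (mean centred log2 CPM of the members) in each library, by genotype, with replicate numbers, marker shape for the sex label and bars for the mean and SD of 5 libraries. The pigment scores of NPYtet libraries all lie below those of WT libraries, while the other 7 lists overlap between the genotypes.

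Within the sexes, the genotype difference in Npy was alike. Among libraries labelled female (3 NPYtet, 2 WT) Npy had a log2 fold change of 7.46 (SE 1.01, edgeR adjusted p = 0.0814), and among those labelled male (2 NPYtet, 3 WT) it rose by 7.44 (SE 0.84, edgeR adjusted p = 0.0117). In edgeR, 0 genes were called in females and 447 had an unadjusted p under 0.05, 403 of them lower in NPYtet, while DESeq2 called 166. Males had 1 call, Npy, with 724 genes at an unadjusted p under 0.05 and 6 calls in DESeq2. Hair genes were lower in 43 of 43 members among females (median -7.54) and 40 of 43 among males (median -0.87), and pigment genes in 11 and 10 of 13 (medians -1.77 and -1.11). Of the 2 WT females only WT replicate 1 had a high share of hair reads, so the female values for hair genes rest on it. Lipogenesis rose among females (16 of 17 positive, median 0.69, limma adjusted p = 1.27e-12; adjusted p = 0.0221 with an estimated correlation) and did not pass among males, where 10 of 17 were positive. By fry the list did not pass among females (adjusted p = 0.251). The 2 WT females scored -0.754 (WT replicate 1) and -0.182 (WT replicate 3). The 3 NPYtet libraries labelled female include replicate 1, which carries Y-linked reads. In the test of the difference itself, 0 genes had a genotype difference that differed by sex in edgeR, with 294 at an unadjusted p under 0.05 and 3 calls in DESeq2; lists were not tested for it. Without WT replicate 3, 1 of the 2 WT females, 224 genes were called in females and 108 for the interaction; without NPYtet replicate 2, 362 were called in males, and without WT replicate 2, 4 or 5 or NPYtet replicate 5, 0 were. Leaving out WT replicate 3 or NPYtet replicate 2 leaves an arm of 1 library (WT replicate 1 or NPYtet replicate 5), which is assumed to vary like the other groups, so these counts rest on that library.

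Skin labelled male differed from skin labelled female in genes of activated epidermis and of neutrophils. All 27 measured members of the keratinocyte activation list were higher in males, 17 of them called over all genes and 24 when adjusted over the list alone, and the list rose by camera in limma (median 3.85, adjusted p = 2.67e-30; adjusted p = 0.187 with an estimated correlation). Krt16, a keratin of wounded epidermis, averaged 37.2 ± 23.9 CPM in females and 3584 ± 3498 CPM in males (SD, n = 5 each), a log2 fold change of 6.46 (SE 0.88, edgeR adjusted p = 0.00470). Stfa1 and BC100530, stefin protease inhibitors, rose by 7.06 (SE 1.18) and 6.58 (SE 1.12), and the neutrophil chemokine Cxcl2 rose by 6.74 (SE 0.77). Stfa1 lost its call without WT replicate 3 (6.98), NPYtet replicate 2 (7.03) or NPYtet replicate 3 (6.93), and BC100530 without WT replicate 3 (6.09) or NPYtet replicate 2 (6.93). Il24, a cytokine of the interleukin 10 family, averaged 0.00492 ± 0.0110 CPM in females and 5.94 ± 5.55 CPM in males (SD, n = 5 each; edgeR adjusted p = 0.00218). Neutrophil genes rose in males, with 7 of 11 called (median 3.05, limma adjusted p = 1.83e-12; adjusted p = 0.241 with an estimated correlation), including S100a8 at 5.85 and S100a9 at 6.21, calcium-binding proteins that keratinocytes also make. S100a8 and S100a9 belong to the antimicrobial list too, so the results of these lists are not separate. Antimicrobial proteins rose, with 7 of 14 called (median 2.33, limma adjusted p = 5.47e-11; adjusted p = 0.187 with an estimated correlation), and the median was 1.06 without WT replicate 2 and NPYtet replicate 5 and 1.27 with genes at equal depth as a covariate. That covariate ended the calls of Krt16, Stfa1, BC100530, S100a8 and S100a9, while Cxcl2 (7.46) and Il24 (10.27) kept theirs.

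Other genes were higher in skin labelled female. The eosinophil and type 2 list fell in males, with 6 of 17 members called lower (median -1.43, camera in limma adjusted p = 9.88e-05; adjusted p = 0.340 with an estimated correlation), among them the lipoxygenase Alox15 at -3.26. B and plasma cell genes fell, with 2 of 15 called lower (median -1.44, limma adjusted p = 8.37e-05; adjusted p = 0.436 with an estimated correlation). Hamp2, a hepcidin gene, averaged 10.8 ± 6.63 CPM in females and 0.434 ± 0.335 CPM in males (SD, n = 5 each), a log2 fold change of -4.63 (SE 0.72, edgeR adjusted p = 0.00751). Its neighbour Hamp averaged 4.42 ± 4.05 and 0.0602 ± 0.0662 CPM, and Gbp2b, an interferon-induced GTPase, averaged 2.02 ± 0.931 and 0.0232 ± 0.0518 CPM (SD, n = 5 each; edgeR adjusted p = 0.00907 and 0.00470). Akr1c19, a ketosteroid reductase family member, fell by 5.06 (SE 0.79) and the lectin Clec4g fell by 3.28 (SE 0.70). Clec4g lost its call without WT replicate 2, 3 or 5 or NPYtet replicate 3 or 4, with log2 fold changes between -3.43 and -2.64. With the number of genes at equal depth as a covariate, Alox15, Hamp2, Hamp, Gbp2b, Akr1c19 and Clec4g all lost their calls. Hamp2, Hamp, Gbp2b and Akr1c19 each passed in 18 of 20 alternatives. Over these Hamp ran from -5.99 to -2.56 and Gbp2b from -9.11 to -4.02.

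In total 448 genes differed by sex label in edgeR, 246 higher and 202 lower in males, and 332 of them did not overlap between the labels. Of the 53 lists, 23 passed by sex label, 17 higher and 6 lower in males. Hair shaft and inner root sheath genes were among those higher, in 42 of 43 members with 0 called (median 3.34, camera in limma adjusted p = 1.07e-11; adjusted p = 0.535 with an estimated correlation), and the median was 1.23 with the number of genes at equal depth as a covariate, 2.10 without NPYtet replicate 5 and 6.68 without WT replicate 1. The Y-linked list passed too (median 4.90, limma adjusted p = 0.00378; adjusted p = 0.531 with an estimated correlation), but its genes were not among the calls, with 0 of 4 called and 0 at an unadjusted p under 0.05; the library labelled female NPYtet replicate 1 carries them. Sex labels went with library measures: WT replicate 2 and NPYtet replicate 5, both male, had the fewest genes with a read, and at equal depth every library labelled male (19953 to 24534 genes) had fewer than every library labelled female (24574 to 25338). The count was 949 without those libraries and NPYtet replicate 1, 11 with the number of genes at equal depth as a covariate and 89 with the ribosomal RNA share as a covariate, and 2316 in DESeq2 and 5590 in limma voom. It was 209 without WT replicate 2, 58 without WT replicate 3, 2725 without WT replicate 4, 269 without WT replicate 5, 97 without NPYtet replicate 3 and 89 without NPYtet replicate 4.

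**Figure D4:**
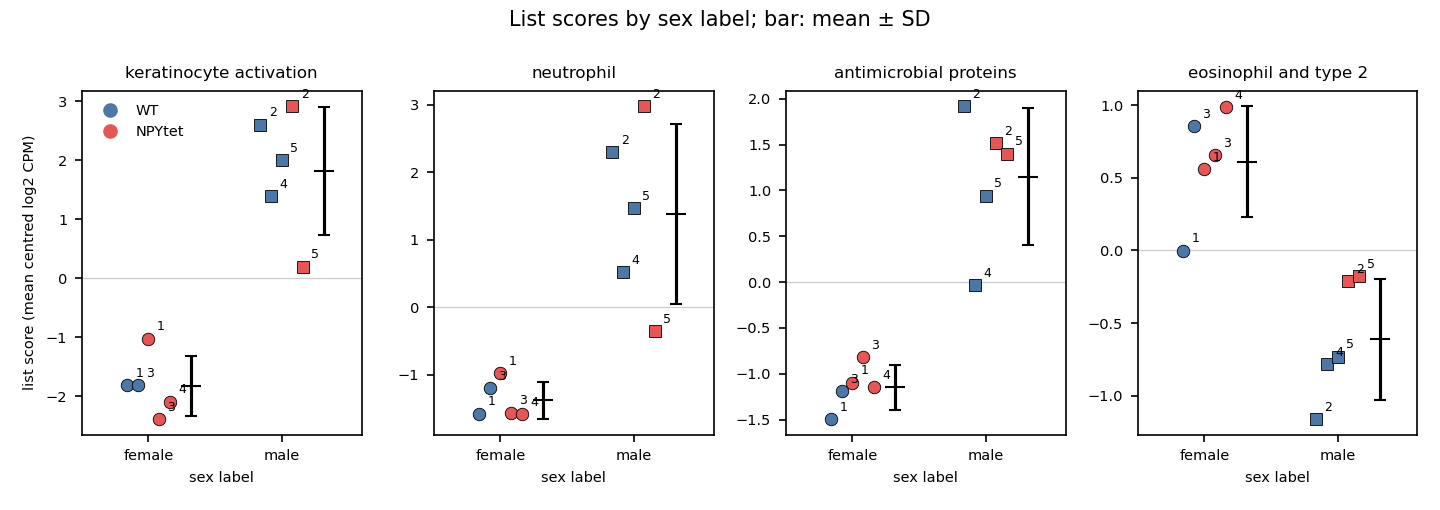
Scores of 4 gene lists (mean centred log2 CPM of the members) in each library, by sex label, with colour for genotype, replicate numbers beside the points and bars for the mean and SD of 5 libraries. The keratinocyte activation, neutrophil and antimicrobial scores of every library labelled male lie above those of every library labelled female, and the order is the opposite for the eosinophil and type 2 list.

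The targeted allele was made in another strain, so sequence linked to Npy can differ between the genotypes, and genes near it were set against the rest. Within 10 Mb on either side of Npy on chromosome 6, 135 other genes were tested, of which 0 were called by edgeR; 6 (4.44%) had an unadjusted p under 0.05, against 3.58% of 17924 genes elsewhere (Fisher's exact test, two-sided, p = 0.489). DESeq2 called 0 genes there besides Npy. The test on called genes could show nothing, since Npy itself was left out and no other gene was called. Chn2, a regulator of Rac signalling, had the smallest p in this window, with a log2 fold change of -1.22 (SE 0.37, edgeR adjusted p = 0.999).

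**Figure D5:**
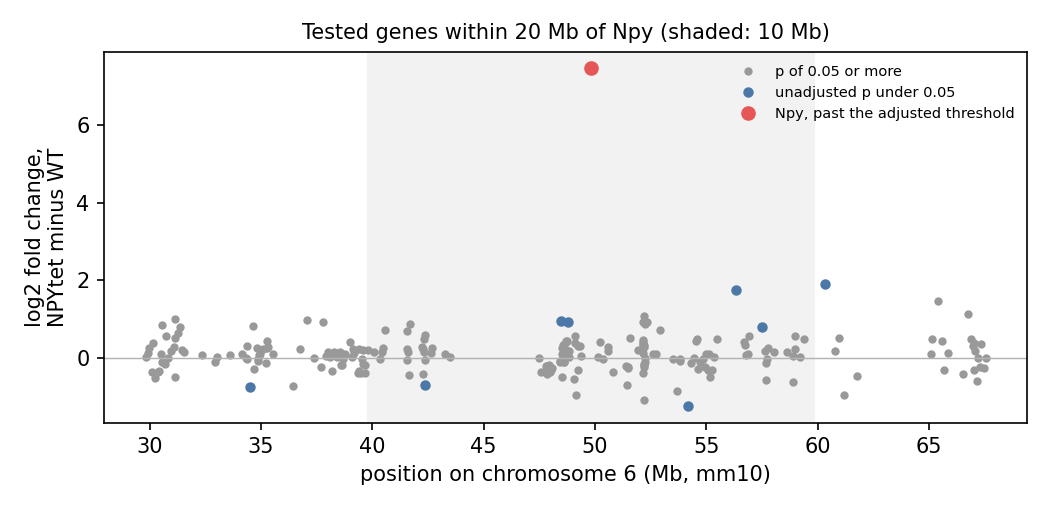
Log2 fold change, NPYtet minus WT, of each tested gene within 20 Mb of Npy against its position on chromosome 6 in Mb (mm10), with the 10 Mb window shaded. Npy stands at 7.45, and 8 other genes in the 20 Mb span have an unadjusted p under 0.05.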

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

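The rule for comparing each library with the others of its genotype was fixed before the data were examined. The measures it was used on included some settled later, such as genes at equal depth and genes named by their p-values. The tests of explanations for the Y-linked reads were chosen only after the result was seen. A library was picked out where its gap to the nearest other was a large share of its group's range. Chance picks out about 1 in 20 groups, and 16 of 158 groups were picked out here. Several measures overlap, such as genes with a read and genes at equal depth, so these 16 are not independent.

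NPYtet replicate 5 was far from the other NPYtet libraries in 7 measures. It had 19953 genes with a read, and the same 19953 at equal depth because it has the smallest total, against 24803 and 24091 in the next lowest. Mitochondrial genes took 9.26% of its reads, the ribosomal RNA locus 4.70%, Lars2 4.79% and hair list genes 1.57%. Its thermogenic adipocyte score was 0.795. WT replicate 2 stood apart from the other WT libraries at 1.82% of reads at the ribosomal RNA locus and 1.54% on Lars2.

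WT replicate 3 had the lowest hair score of the WT libraries, -3.04 against 1.99 in the next, and the lowest Npy, a log2 CPM of -2.75 against 0.46. NPYtet replicate 2 had the highest scores of its group for inflammatory cytokines and NF-kB response, 1.37 against -0.23, and for neutrophil genes, 2.98 against -0.36. Its NPY system score was the lowest at -0.10, as were its log2 CPM of Lce1m, 7.89, and of Retnla, 5.94. In edgeR with the main filter, 0 genes had a genotype difference that differed by sex.

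The library labelled female NPYtet replicate 1 carried Y-linked reads at the level of males. RNA of a male mixed into a female library would keep Xist, and its Xist was 0.0147% of the lowest other library labelled female. An exchange with another of the 10 libraries needs a library labelled male that lacks Ddx3y or carries Xist, and there were 0. A wrong sex label of this library alone, or an exchange with a sample from outside the 10, could account for Ddx3y at 37.2 CPM, within the range of the libraries labelled male. Yet its scores lay with the libraries labelled female for keratinocyte activation (-1.023, males 0.195 to 2.919), neutrophil (-0.982, males -0.359 to 2.977) and eosinophil genes (0.56, males -1.161 to -0.177). These last 2 explanations stay open, and no biological explanation was tested.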

How the results depend on the processing

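Alternatives were fixed before the data were examined, except 4 chosen after seeing the data: leaving out WT 2 and NPYtet 5, leaving out these and NPYtet 1, and covariates for the ribosomal RNA share and for genes at equal depth. Causes of the changes below were not tested unless stated. Npy was past the threshold in 25 of 26 alternatives, with log2 fold changes of 7.09 to 8.17 with each library left out and 7.18 to 8.48 otherwise. The exception left out 3 libraries (7.45, edgeR adjusted p = 0.133, within 1.20e-51 to 0.133), where 7 libraries remain. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.256, 0.304, 0.644, 0.093 and 0.076 across genes. With a replicate block 1 gene was called, Npy was at 7.51 and 20 lists passed, 12 up and 8 down against 16 and 4: matrix, antimicrobial, MHC class II, complement and NF-kB lists lost their calls, and interferon and keratinocyte activation passed downward. With the block and no sex term the values were 1, 7.29 and 22. The unstranded alternative was not run.

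Counts of genes differing by genotype were 35 in DESeq2, 2 in limma voom, 409 with no filter on low counts and 0 without the 3 libraries, and 1 to 8 with each library left out. Those differing by sex numbered 2316, 5590 and 2380 in these settings, 949 without the 3 libraries, 89 with the ribosomal RNA covariate and 11 with genes at equal depth as covariate, and 58 to 2725 with each library left out. Called genes in females were 166 in DESeq2, 338 unfiltered and 0 to 224 with each library left out; in males they were 6, 88 and 0 to 362; for the interaction 3, 217 and 0 to 108. Where a library left out leaves 1 in an arm, that library is assumed to vary like the other groups. Gene lists passing numbered 0 with camera and an estimated correlation, 0 with fry, 14 with the hair covariate, 15 with the adipocyte covariate, and 16 to 32 with each library left out. The share of called genes beside Npy was 0 at 5, 10 and 20 Mb and at adjusted p under 0.1, with no genes called there to compare.

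Of 1118 values for named genes by genotype, 1062 kept direction and side of the threshold, and 39 passed only under the alternative; of 258 by sex, 28 no longer passed. By genotype only Npy was called in the main fit, so keeping the side mostly meant staying uncalled. Of 702 values for lists by genotype, 529 kept both, 103 no longer passed and 24 passed only under the alternative; of 234 for lists by sex, 226 kept both, 7 no longer passed and ribosomal proteins turned (-0.062) with genes at equal depth as covariate. By genotype the direction turned in 46 list values and 16 gene values, some past the threshold in the main fit or in the alternative; list values are medians, and the list test can turn without its median. In DESeq2 these were interferon response (0.091) and keratinocyte activation (0.058); in limma voom Dpp4 (-0.051) and Pyy (-2.30). With no sex term they were neutrophil (0.014), type 17 (0.10) and skeletal muscle (-0.15); with the replicate block neutrophil (-0.12) and type 17 (-0.068); with the block and no sex term neutrophil (-0.36), type 17 (-0.077) and muscle (0.027). The muscle covariate turned muscle itself (0.026) and Pyy (-0.11). The hair covariate turned the hair list itself (-0.088), complement (-0.18), NF-kB response (-0.11), T cell (-0.10), macrophage (-0.18), neutrophil (-0.18), type 17 (-0.38) and Pyy (-0.41). The adipocyte covariate turned adipocyte genes themselves (-0.058), interferon (0.18) and keratinocyte activation (0.014). A list used as its own covariate loses its difference by construction.

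Leaving out WT 2 and NPYtet 5 turned interferon (0.16), keratinocyte activation (0.38), muscle (0.083), Dpp4 (-0.22) and Pyy (-0.78); without NPYtet 1 as well the same 5 were at 0.24, 0.27, 0.12, -0.09 and -2.33. The ribosomal RNA covariate turned interferon (0.002), keratinocyte activation (-0.062) and Pyy (-0.68), and genes at equal depth interferon (-0.009) and Pyy (-0.54). With each library left out in turn, the lists and genes that turned ran from -0.48 (without NPYtet 2) to 0.24 for interferon, -0.72 to 0.45 for keratinocyte activation, -0.40 to 0.62 for type 17, -0.84 to 0.82 for neutrophil, -0.40 to 0.11 for muscle, -0.18 to 0.52 for NF-kB response, -0.090 to 0.39 for Dpp4 and -0.79 to 1.004 for Pyy. Small changes can be missed: 3 of 50 simulated 2-fold changes were recovered, against 47 of 50 at 8-fold. The simulated libraries lacked the sex and tissue differences of the real ones, so large changes can be missed too. Tyrp1 at -4.40 and Pmel at -3.35 were not called in the main edgeR fit.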

Other observations

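All tests of explanations in this part, the divisions of the libraries included, were run or labelled only after the result was seen, and the gene lists were fixed before the data were examined.

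Of the lists that differed between skin labelled male and female, some go with library quality. Oxidative phosphorylation genes were higher in males in 28 of 31 members (median 0.64, camera in limma adjusted p = 2.38e-05; adjusted p = 0.533 with an estimated correlation), and ribosomal protein genes in 25 of 27 (median 0.81, limma adjusted p = 3.17e-05; adjusted p = 0.614 with an estimated correlation). The scores were highest in NPYtet replicate 5 (0.828 and 1.198) and WT replicate 2 (0.524 and 0.396), while the male NPYtet replicate 2 (-0.157 and -0.437) lay within the range of the females, and neither list passed with the number of genes at equal depth (medians 0.12 and -0.06) or the ribosomal RNA share (0.17 and 0.06) as a covariate, nor did ribosomal proteins without NPYtet replicate 5 (0.28). Inflammatory cytokine and NF-kB response genes were higher in 27 of 31, with 6 called (median 0.81, limma adjusted p = 1.94e-05; adjusted p = 0.531 with an estimated correlation; median 0.46 without NPYtet replicate 2). Glucocorticoid response genes were higher in 13 of 14, with 3 called (median 0.86, limma adjusted p = 3.17e-05; adjusted p = 0.241 with an estimated correlation). Matrix remodelling and wound response genes had 6 of 20 called higher (median 0.92, limma adjusted p = 6.42e-05; adjusted p = 0.531 with an estimated correlation; median 0.60 without NPYtet replicate 2). Schwann cell and nerve genes were lower in 15 of 16 (median -0.48, limma adjusted p = 0.00793; adjusted p = 0.340 with an estimated correlation), a call lost without NPYtet replicate 2 (-0.54), and T cell genes in 18 of 22 (median -0.60, limma adjusted p = 0.00830; adjusted p = 0.581 with an estimated correlation).

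Lower pigment genes in every NPYtet library are the pattern by genotype, besides Npy, that other data would most need to address. Chance is not excluded. The exact permutation p of the pigment score was 0.00794, the smallest it can give, and 0.210 after adjustment over the 53 lists. At that smallest value a list passes the adjustment only if several others reach it too, so the adjusted value cannot decide. Hair follicles hold most melanocytes of mouse skin, so the stage or number of hair follicles could lower them; at equal hair score the pigment score differed by -1.21 (SE 0.61) instead of -1.44 (SE 0.49), and the exact permutation p of what the hair score left was 0.159. That test decides neither way, since the hair score is itself tied to genotype, and the list's median went from -1.27 to -0.78 in the fit with that covariate (camera in limma adjusted p = 0.0045, within 2.70e-20 to 0.428 over all alternatives). The 2 libraries with the highest ribosomal RNA share are not needed, as the median was -2.19 without them. Of the 13 members, 0 lie within 20 Mb of Npy. Map positions fixed that count beforehand, so it is no test of donor sequence on these data. That count depends on which genes the list holds. It leaves open effects through other genes near Npy, and donor sequence elsewhere was not examined. An effect of the genotype, on melanocytes or through the hair cycle, remains a hypothesis that these data cannot tell from follicle stage.

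Library measures differ by sex label, and so do activated-keratinocyte and neutrophil genes. NPYtet replicate 5, with the fewest genes, had the lowest of the male scores (0.195 and -0.359). WT replicate 2, with the next fewest, had the highest of the WT scores (2.606 and 2.297). With the number of genes at equal depth as a covariate, the keratinocyte activation median was 4.27, against 3.85 before. A straight-line effect of that number therefore did not account for the difference. Since the labels do not overlap in that number, the fit extrapolates, and RNA quality or library yield cannot be excluded as the cause. For the 448 called genes, library yield and sex cannot be told apart: 10 were still called with that covariate and 447 kept their direction, while the median size of the log2 fold change went from 2.10 to 1.72 and its SE from 0.443 to 0.520, so the calls ended through both a smaller estimate and a wider error. A fit with a grouping of the libraries taken from the divisions below was also looked at and set aside, because that grouping came from the outcome. Sex of the animals, and fighting wounds or housing, which the labels do not give, stay open as untested. The library labelled female NPYtet replicate 1, with Y-linked reads and almost no Xist, scored with the females (keratinocyte activation -1.023, neutrophil -0.982), so in it the pattern follows the label and not the X- and Y-linked reads.

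Dividing the 10 libraries in other ways tested whether chance could give as much. For genes by genotype, 3 of 100 divisions, the real one included, called at least the real 1 gene, and the highest other called 166; since that gene is Npy, the altered locus, the count adds nothing to the result for Npy. That division set WT replicates 1, 2, 4 and 5 with NPYtet replicate 5, the libraries with over 1% of reads on hair genes, which points to a structure of the samples that genotype follows only in part. For lists by genotype, 37 of 100 divisions passed at least the real 20, with 35 in the highest other, so chance cannot be excluded for the number of lists. For genes by sex, 2 of 100 called at least the real 448, and the highest other called 3568, with WT replicates 1, 3 and 4 and NPYtet replicates 3 and 4 on 1 side. Those 5 had the most genes with a read, again a structure of the samples.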
